A study of Mus musculus with 4 samples.

How the data were processed

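Liver RNA from 4 groups of mice was sequenced, with 1 sample per group. Per the submitters' processing notes, the reads were processed with DRAGEN, a read alignment and quantification platform, and GRCm38 is the genome build named. The aligner settings, the annotation release and the filters are not given in the sources used here. The deposited table lists genes in rows. It has, per the file headers, 4 columns of TPM, 4 columns of counts, and annotation columns that belong to no sample. TPM is a transcript abundance: reads divided by gene length, then scaled by the library's sum of these length-divided values.

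The 8 columns of per-sample values were not used here. Per the file headers, their names hold a shared code, a number and a letter. A search for these column names in the sample labels and the series text found 0 of them. The order of the columns and the expression levels in them were not taken as evidence for which sample a column holds, because a wrong assignment could exchange diets or genotypes in a comparison. The depth of each library and the precision it gives are therefore not reported.

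The annotation columns (gene identifier, symbol, type, position, strand and length) were read with Python 3.11.15 and pandas 2.3.3. The gene identifiers, with their version numbers, were looked up in GENCODE release M21, an annotation of GRCm38. Of 55487 identifiers, 54435 were found there, and 54435 of these had the same chromosome, start, end and strand in both. The other 1052 were not found there with their version number, and some of them were not found with it ignored either.

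Before the data were examined, the samples were placed in groups from their titles, and comparisons of diet within each genotype, of genotype within each diet, and of the diet effects between genotypes were planned. With 1 sample per group, these were to be given as sizes with counting error and without p-values. An additive fit of genotype and diet over all 4 libraries was the only planned source of p-values. That fit assumes the same diet effect in both genotypes and reads any genotype-dependent effect as error. A total of 38 gene lists holding 789 different symbols had been fixed, of which 787 are in the table's symbol column. The genes to be named were to be those with the most extreme ratios in each comparison, the list members with the largest ratios, and Pdpk1, Xist and Ddx3y. None of these comparisons was run.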

Results

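The liver transcriptome was profiled by RNA sequencing in mice that differed in genotype and diet. Control mice and A-PDK1KO mice were weaned at 4 weeks of age and then received normal chow or the GAN diet for 16 weeks. The GAN diet is an obesogenic diet rich in fat, fructose and cholesterol that is used to induce non-alcoholic steatohepatitis (NASH), a fatty liver disease with inflammation. The 4 groups were control mice on normal chow, control mice on the GAN diet, A-PDK1KO mice on normal chow and A-PDK1KO mice on the GAN diet. Each group had 1 sample, so no difference between any pair of groups has a replicate check.

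The design addresses how insulin resistance of adipose tissue affects gene expression in the liver when NASH is induced by diet. PDK1 here is the phosphoinositide-dependent protein kinase that phosphorylates AKT in the insulin signalling pathway, and it is encoded by Pdpk1. The planned analysis took A-PDK1KO to mean a deletion of this gene in adipose tissue, from the study's title. In the table, Pdpk1 (ENSMUSG00000024122.16) is a protein-coding gene on the minus strand of chromosome 17, from 24073680 to 24150924 in GRCm38. Its listed gene length of 7161 bases is shorter than the span of these coordinates, so it is not the length of the whole locus. The study's title places the insulin resistance in adipose tissue, so a Pdpk1 level in liver would not by itself check the genotype of a sample.

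The expression table covers 55487 genes, of which 21936 are typed as protein-coding. Its per-sample columns bear names that match no sample label, and their values were not used here. The effect of the GAN diet in control mice, its effect in A-PDK1KO mice, the effect of genotype on either diet and the difference between the diet effects are therefore not analysed here, and no gene or gene group is reported as higher or lower in any group.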

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

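The planned normalization, pseudocount, filter on low values and tools were not applied, because no column of values was assigned to a sample. One alternative was chosen after seeing the data. With the version number ignored, 55227 of the 55487 gene identifiers were found in GENCODE M21, against 54435 with it. No paired analysis was planned or run. The sample titles give no pairing of animals, and each group has only 1 sample.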
